A study of Mus musculus with 4 samples.

How the data were processed

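RNA was measured by sequencing in the stromal vascular fraction of inguinal white adipose tissue from mice, in 2 libraries from animals given a medicinal herb extract (MHE) and 2 from animals given phosphate-buffered saline (PBS). Per the labels' protocols, total RNA was isolated with Trizol and libraries followed standard Illumina procedures. The same protocols speak of triplicate libraries per treatment, and 2 per group were analysed here. Per the submitters' processing notes, TopHat2, edgeR and limma were used and the genome build was mm10, with no versions. The counting program, the annotation and the use of strand are not given in the sources used here, so reads of antisense, overlapping or near-identical genes cannot be separated.

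The authors deposited whole-number read counts per gene symbol, not normalized, for 26214 symbols in each of 4 files. Libraries held 31052064 and 27161882 counts (MHE) and 27695144 and 33391075 counts (PBS). No mitochondrially encoded gene was among the listed symbols. Of the symbols, 26167 matched the RefSeq gene table of GRCm38.p6, the assembly that mm10 is made from, and coordinates come from that table.

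From these counts, edgeR 4.0.16 in R 4.3.3 was used with filterByExpr (minimum count 10, minimum total 15), TMM factors, estimateDisp and a robust quasi-likelihood fit and test with the package defaults. Adjusted p is Benjamini-Hochberg over the 16196 genes tested, with a threshold of 0.05. Log2 fold changes are MHE minus PBS, each standard error (SE) is the size of the log2 fold change divided by the square root of its F statistic, and CPM is the usual depth-scaled count, computed with the TMM factors and given as mean ± SD with n = 2. The biological coefficient of variation was 33.6% and the median prior degrees of freedom 3.13. TMM factors were 1.070 and 1.049 for MHE, and 1.005 and 0.886 for PBS.

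Before the data were examined, 24 gene lists and 18 cell type marker lists were fixed, as were the tests, the other settings to be tried and the rule for named genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, against all tested genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 41 lists tested. The mesothelial list had 2 tested members and was not tested. Camera with an estimated correlation, and fry, were alternatives. The share of each library's counts in a marker list is given with an exact Clopper-Pearson 95% interval. Intervals and floors cover counting error only. A floor of 3 counts over the group stands in for a group without counts.

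The rule for named genes took, among genes past the threshold with a mean log2 CPM of at least 1 and both MHE libraries on the same side of both PBS libraries, the 12 highest and 12 lowest log2 fold changes, leaving out provisional symbols. It also allowed up to 4 members with the smallest p of each list described, and 5 genes that check the animals' sex. Genes named outside that rule are said to be so, and some genes that meet it are not reported here.

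The alternatives were median-of-ratios factors, library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (CPM of at least 1 in 2 libraries and 50 counts in total), the replicate number as a block, and each library left out in turn. Leaving out a library leaves a single one in its group, so the spread comes from the other group alone. Genes said to pass without a PBS library are thus judged on the spread of the MHE libraries only. The legacy setting of the quasi-likelihood fit, chosen beforehand as a comparison, is the default of the installed version and so equals the fit used here. The newer setting was added after seeing the data.

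The procedure was tested on simulated data: 10 draws of counts for the 16196 genes with 200 changed genes each. It recovered 3.89% of genes changed 2-fold, 59.1% changed 4-fold, 92.0% changed 16-fold and 95.9% changed 64-fold. Of the 1372 calls over those draws, 150 (10.9%) were unchanged genes. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom between 139 and 545. The labels call the libraries biological replicates, so p-values measure the spread between them, and an exact permutation of 2 against 2 libraries cannot give a two-sided p under 0.333.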

Results

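RNA-seq counts from 4 libraries of mouse inguinal fat described how gene expression differed between animals given a medicinal herb extract and animals given saline. The stromal vascular fraction is what remains of digested fat once floating adipocytes are removed, and it holds progenitors, vessels and immune cells. Yet mature adipocyte markers took 1.92% to 3.91% of each library's counts, and progenitor markers 0.164% to 0.266%. Adipocyte transcripts were thus present in every library, and changes in adipocyte and lipid genes cannot be assigned to stromal cells. Composition, dose and duration of the extract are not stated in the labels. Each group had 2 libraries, with totals of 27161882 to 33391075 counts. The adipocyte genes Fabp4, a fatty acid carrier, and Scd1, a fatty acid desaturase, were among the most abundant transcripts, at 0.636% to 1.40% and 1.32% to 5.72% of each library's counts, and were named after their values were seen. Replicates correlated at r = 0.971 (MHE) and 0.942 (PBS) over log2 CPM of genes, and libraries of different groups at 0.864 to 0.896, where genes are not independent replicates. Transcripts of the Y chromosome were present in every library (Ddx3y at 2434 to 3228 counts, Uty at 470 to 694, Kdm5d at 456 to 895, Eif2s3y at 1034 to 1292) and Xist had 0 to 5 counts.

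Genes of lymphocytes were much higher with the extract than with saline. All 12 tested T cell markers rose, among them the CD8 co-receptor gene Cd8a, which stood at 134 ± 37.8 CPM with the extract and 2.43 ± 0.755 CPM with saline (n = 2 each). The B cell complement receptor Cr2 and the lymph node venule mucin Glycam1 rose as well, while the adipocyte hormone gene Lep fell from 4587 ± 1165 to 697 ± 91.3 CPM. In all, 799 of 16196 genes passed the edgeR quasi-likelihood test, 643 of them (80.5%) higher with the extract and 156 lower, and all 799 differed at least 2-fold. Without MHE replicate 1 or MHE replicate 2 the count was 0 (2352 and 2596 genes at an unadjusted p under 0.05, against 4626 with all libraries), and it was 2750 without PBS replicate 1 (1753 higher and 997 lower) and 2513 without PBS replicate 2 (1280 higher and 1233 lower, so that 50.9% were higher). The groups did not overlap in 62.0% of tested genes, where chance gives 33.3% for a single gene. Genes are not independent replicates, so the excess over that share does not measure chance.

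**Figure D1:**
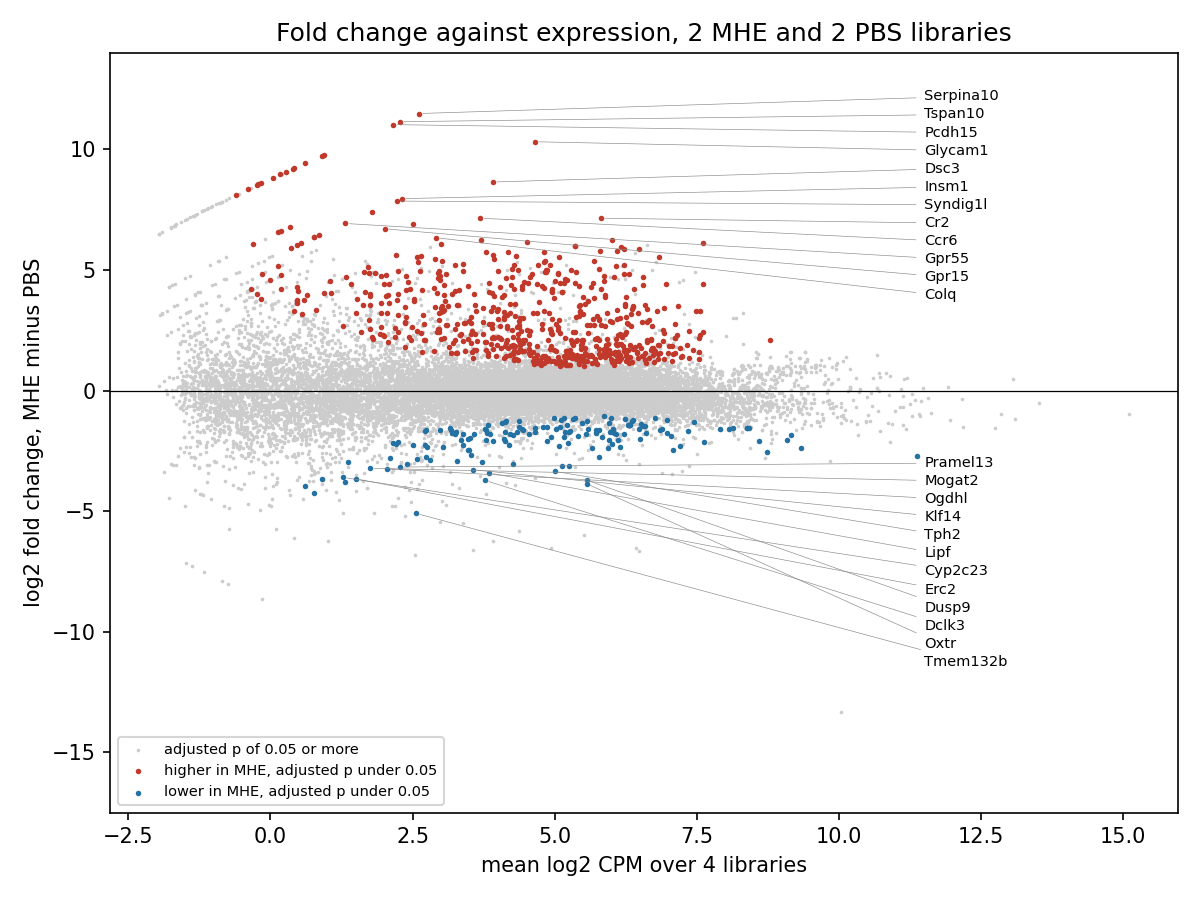
Log2 fold change (MHE minus PBS) against mean log2 CPM for the 16196 tested genes, with the 643 higher genes in red, the 156 lower in blue and the 24 genes of the size rule named. Genes along the upper left diagonal have no counts in PBS, so their fitted values are no bound.

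Several of the largest increases were in genes with hardly a count in saline libraries. Serpina10, a circulating protease inhibitor (chromosome 12, 103616675 to 103631490 in mm10), had 12.1 ± 0.479 CPM with the extract and 0 counts with saline, at least 231-fold higher (adjusted p = 0.0192). Tspan10, a tetraspanin, and Pcdh15, a protocadherin of the inner ear, likewise had 0 counts with saline and were at least 183-fold and 169-fold higher. Glycam1 (chromosome 15, 103562759 to 103565081) stood at 50.1 ± 31.1 CPM against 2 counts in all with saline, a ratio of 1484 with a 95% counting interval of 410 to 12260. It had 72.1 and 28.1 CPM in MHE replicates 1 and 2. Its log2 fold change was 10.32 with all libraries, 9.49 without MHE replicate 1 and 9.37 without PBS replicate 2. The ratios for the transcription factor gene Insm1, for Syndig1l and for the receptor gene Gpr55, also on 2 counts with saline, were 282 (77.8 to 2336), 267 (73.7 to 2213) and 138 (38.0 to 1148). For these 4 genes both counts lay in PBS replicate 1.

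Among the other large increases were lymphoid genes. Cr2 (chromosome 1, 195136811 to 195176880) stood at 112 ± 1.48 against 0.787 ± 0.827 CPM, a log2 fold change of 7.15 ± 0.82 (SE), and Ccr6, a chemokine receptor of B cells and some T cells, rose by the same log2 amount (7.15 ± 0.43). Gpr15, a homing receptor of T cells, rose by 6.71 ± 0.99, the desmosomal cadherin Dsc3 by 8.65 ± 0.76 and the collagen tail of acetylcholinesterase, Colq, by 6.34 ± 0.80. Their adjusted p lay between 0.0192 and 0.0381. Without PBS replicate 1, Cr2 and Colq had 9.06 and 8.58, and without PBS replicate 2, Cr2, Gpr15, Dsc3 and Colq had 6.35, 5.73, 7.66 and 5.49. PBS replicate 2 had 0 counts of Gpr15 and Dsc3, so their fitted values without PBS replicate 1 are no bound and are not given. Cr2, Ccr6, Gpr55 and Pcdh15 overlap provisional gene models, and without strand the reads cannot be assigned between them.

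The lowest genes were led by Tmem132b, a membrane protein gene (log2 fold change -5.09 ± 0.49), the oxytocin receptor gene Oxtr and the kinase gene Dclk3 (-3.72 ± 0.66). Oxtr (chromosome 6, 112473683 to 112491035) stood at 6.07 ± 2.84 CPM with the extract and 87.9 ± 12.3 CPM with saline (adjusted p = 0.0219), and the phosphatase gene Dusp9 (chromosome X, 73639389 to 73643514) at 6.69 ± 0.314 and 87.6 ± 10.4 CPM (adjusted p = 0.0192). Klf14, a transcription factor of fat, had a log2 fold change of -3.28 ± 0.39, the monoacylglycerol acyltransferase gene Mogat2 -3.22 ± 0.50, the gastric lipase gene Lipf -3.42 ± 0.39 and Tph2, a serotonin synthesis enzyme, -3.35 ± 0.31. Erc2, Cyp2c23, Ogdhl and Pramel13 lay between -3.66 and -3.17. Erc2 and Tmem132b overlap other gene models, and Dclk3 lost its call without PBS replicate 2 (adjusted p = 0.0527) and without the low-count filter (0.0608). Without MHE replicates 1 and 2, Dclk3 had -3.03 and -4.99.

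**Figure D2:**
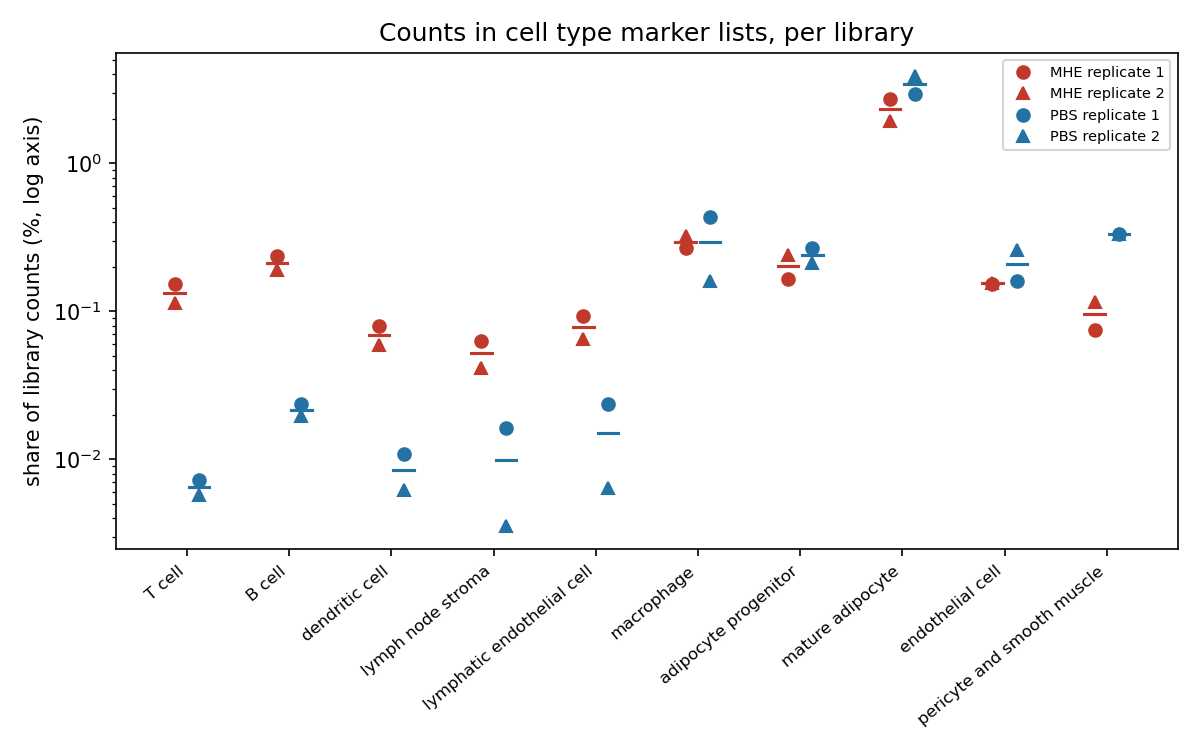
Share of each library's counts (percent, log axis) in 10 cell type marker lists, where circles are replicate 1, triangles replicate 2 and bars the mean of the 2 libraries. T cell markers take 0.133% of counts in MHE and 0.00645% in PBS, while macrophage markers take 0.296% and 0.295%, the latter the mean of 0.430% in PBS replicate 1 and 0.161% in PBS replicate 2.

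Marker lists of lymphoid cells and of lymph nodes were higher with the extract. All 12 of the T cell markers rose over all genes tested and also adjusted over the list alone, with a median log2 fold change of 5.09; Cd8b1, the signalling gene Themis and the costimulatory receptor Cd28 rose by 5.99, 5.75 and 3.69. Of 12 B cell markers, 4 rose (11 adjusted over the list alone, median 4.65): Cr2, Bank1 (4.20), Fcer2a (6.24) and Cd22 (4.71). Of 11 dendritic cell markers, 6 rose (10 adjusted over the list alone, median 3.28), including Itgae, Siglech, Flt3 and Xcr1 at 4.02, 3.97, 3.28 and 3.34. The camera test with a preset correlation gave adjusted p = 6.14e-09, 6.45e-05 and 1.01e-05 for these lists, and each had adjusted p = 0.72 with an estimated correlation. Without PBS replicate 1 the T and B cell medians were 6.27 and 8.17, and Themis, Bank1, Fcer2a, Cd22 and Flt3 had 6.67, 4.97, 8.38, 6.30 and 3.92. Without PBS replicate 2 those medians were 4.46 and 3.84 and Fcer2a and Cd22 had 5.41 and 3.98, without MHE replicate 1 Siglech had 3.22, and without the low-count filter Fcer2a and Cd22 lost their calls (adjusted p = 0.0714 and 0.0727).

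Of 6 lymph node stroma markers, 3 rose (4 adjusted over the list alone, median 3.23): Glycam1, the B cell chemokine Cxcl13 (2.38 ± 0.33) and Tnfsf11 (4.50 ± 0.79). Of 12 markers of NK and innate lymphoid cells, 3 rose (6 adjusted over the list alone, median 1.64): Eomes, Il18r1 and the perforin gene Prf1, at 4.37, 3.03 and 3.41. Of 8 lymphatic endothelial markers, Lyve1 rose (1.67 ± 0.20; 4 of 8 adjusted over the list alone, median 1.68), and Prox1 had 3.50 ± 0.76 at an adjusted p of 0.0675. Camera adjusted p was 0.001, 3.55e-04 and 0.0111, and adjusted p = 0.72 with an estimated correlation for each list. Without PBS replicate 1 their medians were 4.92, 2.59 and 3.21, and Tnfsf11 had 6.16, against 3.74 without PBS replicate 2. Prox1 passed without PBS replicate 1 (5.06) and without PBS replicate 2 (2.77). Between the saline libraries, lymph node stroma markers took 0.0162% (95% interval 0.0157 to 0.0166) of counts in PBS replicate 1 and 0.00353% (0.00333 to 0.00374) in PBS replicate 2.

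Immune signalling lists were higher along with the lymphoid markers. Of 12 genes of antigen presentation by MHC class II, 2 rose (8 adjusted over the list alone, median 1.41), the transactivator Ciita (2.84 ± 0.35) and Cd86 (2.33 ± 0.29), while H2-Ob, from a family of similar genes, had 5.02 ± 1.01 at an adjusted p of 0.0592. Of 10 type 2 and regulatory lymphocyte genes, 5 rose (7 adjusted over the list alone, median 1.36), among them the regulatory T cell genes Ctla4, Tnfrsf18, Ikzf2 and Foxp3 at 4.17, 3.49, 2.02 and 1.30. Of 20 classical inflammatory genes, 3 rose (7 higher and 1 lower adjusted over the list alone, median 1.52), the chemokines Ccl5 (110 ± 7.03 against 7.41 ± 4.94 CPM) and Cxcl10 and the cytokine Il1a, and Tnf had 2.83 ± 0.57 at an adjusted p of 0.0584. Of 22 interferon response genes, 4 rose (7 higher and 1 lower adjusted over the list alone, median 0.72), among them Cxcl10, Mx1 and Irf1, at 2.22, 2.41 and 1.35. Camera adjusted p was 3.01e-04, 5.02e-04, 0.0125 and 7.65e-04, with adjusted p = 0.72 with an estimated correlation for each, and the inflammatory list had adjusted p = 0.0899 without PBS replicate 2. Without MHE replicate 2 the inflammatory median was 0.31 (adjusted p = 0.0439), and without PBS replicate 1 that of the type 2 and regulatory list was 2.15, with Ctla4 at 4.83 and Ccl5 at 4.79. Il1a had adjusted p = 0.0502 without the low-count filter, and H2-Ob and Tnf passed without PBS replicate 1 (7.14 and 3.55) and without PBS replicate 2 (4.20 and 2.36).

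Lists for growth and acute stress were also higher by camera. None of the 37 cytosolic ribosomal protein genes passed the gene test, over all genes or adjusted over the list alone, yet all 37 had positive log2 fold changes with a median of 0.89 (camera adjusted p = 4.04e-06, adjusted p = 0.72 with an estimated correlation). None of the 30 cell cycle genes passed either way, and 29 were positive (median 0.54, camera adjusted p = 0.0011, adjusted p = 0.732 with an estimated correlation, adjusted p = 0.0585 without PBS replicate 2). The cell cycle median was 1.02 without PBS replicate 1 and 0.28 without PBS replicate 2. Of 23 immediate early and heat shock genes, which tissue digestion can induce, 3 rose (7 higher and 1 lower adjusted over the list alone, median 0.53): Egr3 (31.0 ± 2.44 against 1.58 ± 0.247 CPM), Ier2 (1.24 ± 0.20) and Fosb (3.89 ± 0.67). Camera gave adjusted p = 0.0244, with adjusted p = 0.732 with an estimated correlation, and 0.335 without MHE replicate 2 and 0.102 without PBS replicate 1, and the median was 0.92 without MHE replicate 1. Fosb lost its call without PBS replicate 1 (adjusted p = 0.132), without PBS replicate 2 (0.176), without the low-count filter (0.0579) and with limma-voom (0.0849), and had 4.53 and 2.75 without MHE replicates 1 and 2.

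Adipocyte and lipid lists were lower with the extract. Of 16 mature adipocyte markers, Lep fell by 2.72 on the log2 scale (SE 0.42) and the beta-3 adrenergic receptor gene Adrb3 rose (112 ± 22.4 against 41.1 ± 1.39 CPM), with 1 higher and 2 lower adjusted over the list alone and a median of -0.65. Of 18 lipogenesis genes, the desaturase gene Scd2 fell by 1.61 on the log2 scale (1 adjusted over the list alone, median -0.79), while Fasn, the fatty acid synthase, had -1.80 ± 0.55 at an adjusted p of 0.123. Of 19 cholesterol genes, 2 fell, among them Nsdhl, an enzyme of the late pathway (-1.49 ± 0.22; 7 lower and 1 higher adjusted over the list alone, median -0.76), and the regulator Srebf2 had 1.12 ± 0.20 at an adjusted p of 0.0502. Camera adjusted p was 0.019, 9.55e-04 and 0.00296, each with adjusted p = 0.72 with an estimated correlation. Without PBS replicate 2 the adipocyte list had adjusted p = 0.28 (median -0.25) and the lipogenesis list 0.0506 (median -0.41), and without MHE replicate 2 the adipocyte list had 0.111. Fasn had -2.47 without MHE replicate 2 and passed without PBS replicate 1 (-2.22), and Srebf2 passed without PBS replicate 1 (1.18) and without PBS replicate 2 (1.06).

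None of the 18 fatty acid oxidation genes or 29 oxidative phosphorylation genes passed the gene test, over all genes or adjusted over the list alone, and all 18 and all 29 were negative, with medians of -0.40 and -0.30. Camera gave adjusted p = 0.00984 and 0.0125, and adjusted p = 0.72 and 0.795 with an estimated correlation. The first had adjusted p = 0.0514 without MHE replicate 2 and 0.341 without PBS replicate 2 (median -0.19), and medians of -0.61 and -0.63 without MHE replicate 1 and PBS replicate 1. The second had a median of -0.68 without MHE replicate 1 and adjusted p = 0.28 without PBS replicate 2, and without MHE replicate 2 its direction turned (median 0.05, adjusted p = 0.836).

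Lists of vessels, matrix and lipid-handling macrophages were lower as well. Of 12 pericyte and smooth muscle markers, the actin-binding Lmod1 fell (11.4 ± 4.36 against 56.0 ± 6.16 CPM; 4 adjusted over the list alone, median -1.37), and the smooth muscle actin Acta2 had -2.94 ± 0.64 at an adjusted p of 0.0675. None of the 18 lipid-associated macrophage genes passed (median -1.42), with the cathepsins Ctsl and Ctsd at -1.47 and -1.39 and the lectin Lgals3 at -2.02. None of the 15 endothelial genes (median -0.75), 30 collagen and matrix genes (median -0.67, with Sparc at -1.53) or 22 hypoxia and glycolysis genes (median -0.41) passed, nor did any gene of these last 4 lists adjusted over the list alone. Camera adjusted p was 0.00984, 3.01e-04, 0.0165, 0.0112 and 0.0298, with adjusted p = 0.72, 0.72, 0.732, 0.795 and 0.72 with an estimated correlation.

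The smooth muscle list had adjusted p = 0.0664 without MHE replicate 1. Acta2 had -3.68 without MHE replicate 2 and passed without PBS replicate 1 (-3.41) and without PBS replicate 2 (-2.28). The endothelial list had 0.0553 and 0.0671 without MHE replicates 1 and 2 and 0.39 without PBS replicate 2 (median -0.17), and a median of -1.13 without PBS replicate 1. The lipid-associated macrophage median was -0.83 without PBS replicate 1, with Lgals3 at -0.90, and Lgals3 and Ctsl passed without PBS replicate 2 (-2.64 and -1.58). The matrix list had 0.403 without PBS replicate 2 (median -0.10) and a median of -2.08 without MHE replicate 2, and turned without MHE replicate 1 (median 0.06, adjusted p = 0.614). The hypoxia list had 0.115, 0.189 and 0.0899 without MHE replicate 1, PBS replicate 1 and PBS replicate 2. Beside these lists, smooth muscle markers took 0.332% of counts in PBS replicate 1 and 0.331% in PBS replicate 2. Among them Cnn1 (338 and 2.40 CPM) and Myh11 (521 and 66.6 CPM) were higher in the first, and Acta2 (1025 and 2214 CPM) in the second. The macrophage genes Mmp12 (488 and 60.1 CPM) and Gpnmb (955 and 207 CPM) were higher in PBS replicate 1. Cnn1, Myh11, Mmp12 and Gpnmb were chosen after their values were seen.

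**Figure D3:**
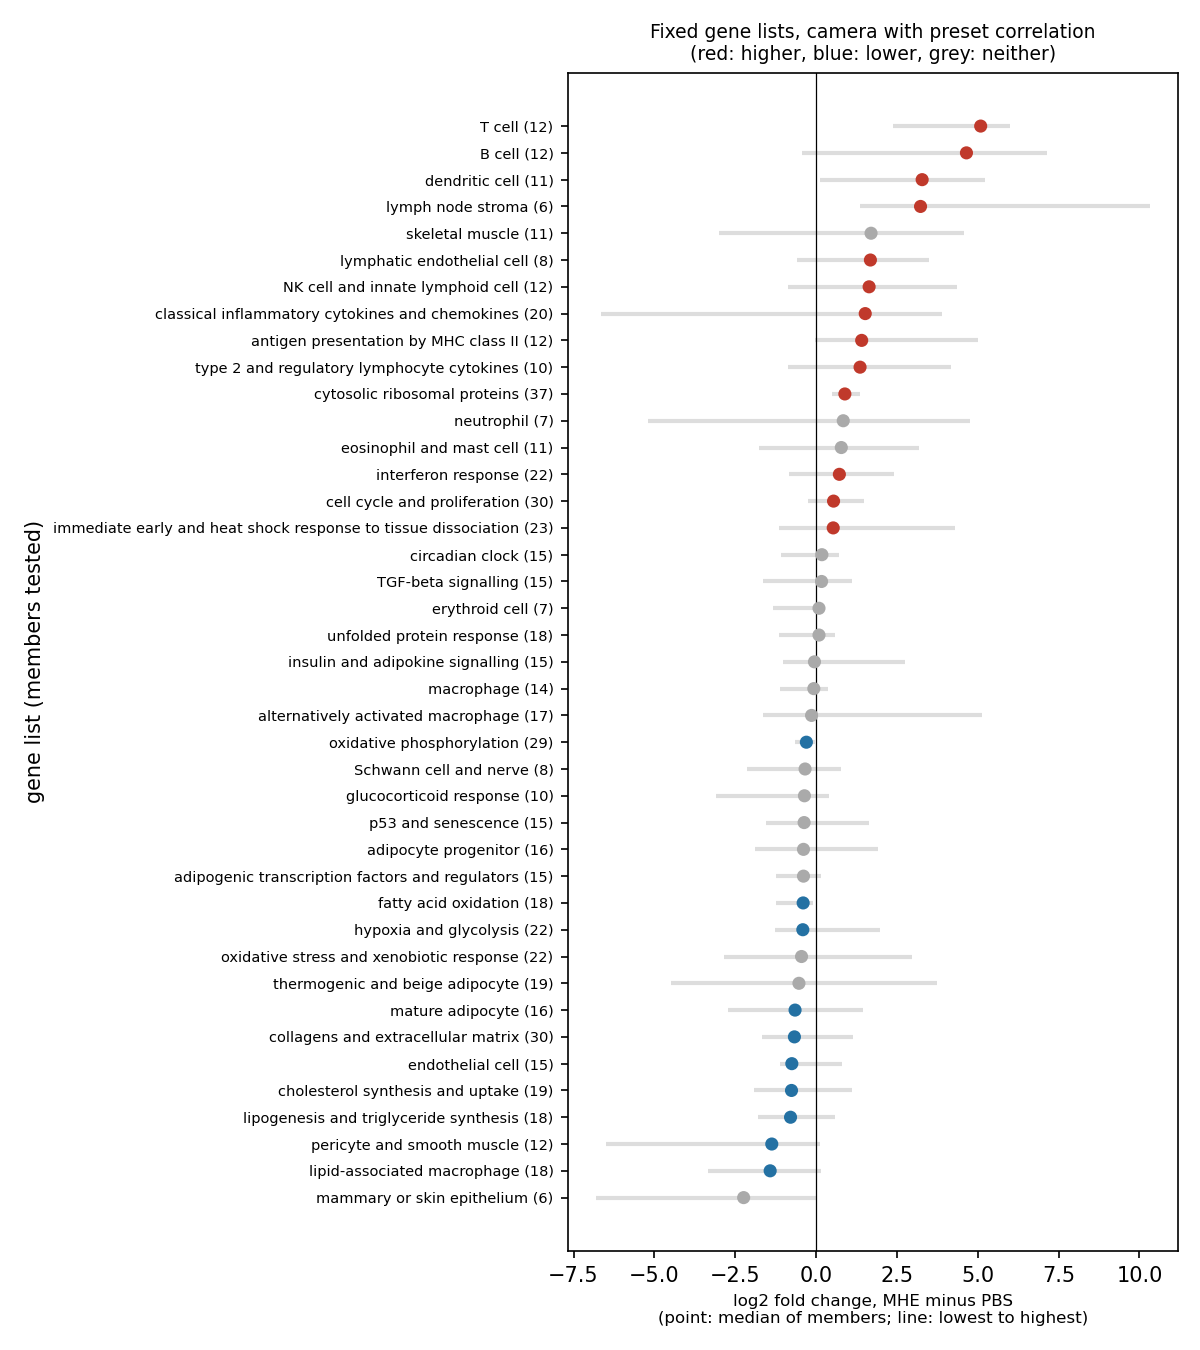
Median log2 fold change (point) and range of members (line) for the 41 tested lists, with tested members in brackets. The T cell list stands highest at 5.09 and the epithelial list lowest at -2.24, the latter not past the camera test.

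The remaining lists did not pass camera. Macrophage markers had a median of -0.07 with 0 of 14 passed either way and took 0.430% of counts in PBS replicate 1 against 0.161% in PBS replicate 2, and the 16 adipocyte progenitor markers -0.39, of which Icam1, an adhesion molecule, rose (1.91 ± 0.20; 3 adjusted over the list alone) and Cd34 had -1.04 ± 0.28 at an adjusted p of 0.0954 and passed without PBS replicate 1 (-1.27). Of 19 thermogenic genes tested out of 22 (median -0.53), Tmem26 and Tnfrsf9 rose (2.78 and 3.75), with 2 higher and 1 lower adjusted over the list alone. Ucp1 of that list, named outside the rule, did not pass the count filter and was not tested. Tnfrsf9 also encodes a costimulatory receptor of activated T cells. Of 22 oxidative stress genes (median -0.45), Gstm2, from a family of similar genes, fell by 1.64, with an adjusted p of 0.0538 under library totals (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0535). None of the 15 adipogenic regulators passed either way (median -0.39, camera adjusted p = 0.0567).

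Single members rose in other lists that did not pass: Pdcd1lg2 (5.14 ± 0.54) of 17 genes of alternatively activated macrophages, Lmnb1 (1.64 ± 0.20) of 15 p53 and senescence genes, Lepr, the leptin receptor (2.76 ± 0.27), of 15 insulin and adipokine genes, and Cxcr2 (4.76 ± 0.35) of 7 neutrophil genes. Adjusted over the list alone, 1, 3, 2 and 1 of these lists' members were higher and 0, 4, 0 and 0 lower. Of 11 skeletal muscle genes, Eno3 and Myh4 rose (2.07 and 4.58; 4 higher and 2 lower adjusted over the list alone), while that list took 0.00920% and 0.0195% of counts in MHE replicates 1 and 2 and 0.0295% and 0.105% in PBS replicates 1 and 2. Myh4 lost its call without the low-count filter (adjusted p = 0.0552) and with limma-voom (0.052), and had 5.54 without PBS replicate 1.

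No member passed over all genes in the lists of TGF-beta signalling (15 tested; 3 higher and 1 lower adjusted over the list alone), unfolded protein response (18), circadian clock (15), glucocorticoid response (10), eosinophils and mast cells (11), epithelium (6), Schwann cells (8; 1 lower adjusted over the list alone), erythroid cells (7) and mesothelium (2; 1 lower adjusted over the list alone). Where not stated, 0 members passed adjusted over the list alone. Their medians were 0.17, 0.09, 0.18, -0.36, 0.78, -2.24, -0.34, 0.09 and -3.60. Mesothelial markers took 0.0148% of counts in PBS replicate 1 and 0.000545% or less in each other library, and the epithelial gene Krt8 stood at 46.4 CPM in PBS replicate 1 and at 0.351 CPM or less in each other library. The median, the mean and the camera direction differed in sign for alternatively activated macrophages (median -0.14, mean 0.14), TGF-beta signalling (mean -0.01), the clock (mean -0.06), insulin signalling (median -0.05, mean 0.09), the unfolded protein response (mean -0.01) and erythroid cells (mean -0.22).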

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

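The fit with the newer quasi-likelihood setting was chosen after seeing the data, and called 953 genes (749 higher, 204 lower). In all 799 genes past the threshold both MHE libraries lay on the same side of both PBS libraries, so leaving out a library could hardly turn a direction. Of 70 genes named by the rule and past the threshold, all 70 kept their direction under every setting run. None of them kept its call without MHE replicate 1 or 2, where a single MHE library is assumed to vary like the PBS libraries. For the list members that did not pass, 19 of those that the rule allowed were followed across the settings. Others that it allowed, such as Me1 of the lipogenesis list, were not followed. All 19 passed with DESeq2, 5 with limma-voom, 5 with the replicate block, 2 with the stricter filter and 2 with the newer setting. With library totals and without the low-count filter 1 passed each, and Srebf2 was among those that passed in each case. Among the 70 named genes past the threshold, calls were lost by 6 without the low-count filter, 1 with library totals, 2 with limma-voom and 14 with the replicate block. The count of changed genes, 799 with all libraries, ranged from 0 to 2750 over the fits that leave out a library, and from 0 to 2714 for those changed at least 2-fold. DESeq2 called 2951 genes (2345 at least 2-fold), 58.1% of them higher against 80.5%, and 798 of the 799 were among them; the cause was not tested. Library totals alone moved the median log2 fold change of all genes from -0.02 to 0.14, with 947 calls. With the replicate block, 764 genes were called, 571 of them also called without it, and 22 of 23 lists kept their call; the numbers are not known to pair animals, and the correlation of replicate differences between groups was 0.12 over genes. Camera with the preset correlation of 0.01 called 23 of 41 lists. With only that setting changed to an estimated correlation, camera called 0 (0 at an unadjusted p under 0.05). The 23 calls thus depend on the preset. Fry called 0 lists (9 at an unadjusted p under 0.05), and why it differed was not tested. Over the fits without a library, the oxidative phosphorylation median ran from -0.68 to 0.05 and that of the matrix list from -2.08 to 0.06, each turned in 1 of them. Taking the 20 most abundant genes out of the totals moved saline shares of T cell markers from 0.00645% to 0.00756%. Saline shares of B cell markers moved from 0.0215% to 0.0252%. With the extract, T cell shares moved from 0.133% to 0.148% and B cell shares from 0.212% to 0.236%. Depth limits genes near the floor, which is 0.0898 to 0.110 CPM for 3 counts in a library.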

Other observations

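The tests of adipocyte share and of scaling below were chosen after the results were seen, while those on the second lymph node and epithelial lists were written before their values were seen. Interferon-inducible genes of the Ifi200 family, named after their values were seen, were split. Ifi206 (58.9 ± 1.53 against 1.59 ± 0.0987 CPM), Ifi208 (log2 fold change 4.24), Ifi209 (3.46), Ifi213 (4.43) and Ifi203 (2.10) rose, with edgeR adjusted p of 0.0192 to 0.0248. Ifi204, Ifi205 and Ifi207 had -0.12, 0.20 and -0.18 and did not pass. These genes are closely related copies, and how the counting divided reads between them is not given, so their values are uncertain. The homing receptor gene Ccr7 of naive lymphocytes, from the dendritic cell list and also named after its value was seen, rose too (log2 fold change 5.21 ± 0.91), with 6.75 and 1.05 CPM in PBS replicates 1 and 2.

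Lymphocyte genes were higher in both MHE libraries. A lower share of adipocyte RNA would raise other cell types alike. The T cell median exceeded the macrophage median by 5.16 on the log2 scale, against an SD of 1.01 over T cell members. Both medians were known when this comparison was chosen, and the SD is over genes, not libraries. Macrophage markers took 0.430% of counts in PBS replicate 1 and 0.161% in PBS replicate 2, so that reference was itself unsteady. The gap shows that macrophage markers did not share the rise, and it is no test of adipocyte share. The T cell median was at least 5.06 under 4 scalings. Those scalings moved the median of all genes only between -0.06 and 0.14, so they could not have undone the rise. They show only that the rise does not depend on which of the 4 was used. A candidate explanation is lymph node tissue in the MHE libraries: a second list of stroma and sinus genes had a median of 1.53, at percentile 99.9 of 10000 expression-matched lists, with 6 of 7 members positive, Siglec1 past the threshold (90.5 ± 1.37 against 29.9 ± 6.53 CPM) and Ubd at -1.97. Saline libraries also held at least 1 CPM of 6 of those 7 genes. The matched lists were drawn gene by gene, so the percentile does not allow for genes that vary together. The second list bears on lymph node tissue in the libraries but cannot separate it from a wider rise of immune genes. Nor does it bear on why that tissue would differ. An effect of the extract on lymphoid cells was not tested. That effect and a difference in how much lymph node was collected are not separated by this design and remain open.

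The epithelial genes Krt8, Cldn3 and Cdh1 stood at 46.4, 21.9 and 16.6 CPM in PBS replicate 1 and at 2.21 CPM or less in the other libraries, while Trf of the same list was higher in PBS replicate 2 (2344 CPM) than in PBS replicate 1 (1664 CPM). Between the PBS libraries, the fixed epithelial list stood 3.70 above the median of all genes on the log2 scale, so its difference was not shared by all genes. That comparison was chosen after the list was seen to stand apart. It could not have come out otherwise and is no test of scaling. A second epithelial list had a median log2 ratio of PBS replicate 1 to replicate 2 of 3.64, with 6 of 7 members positive, so epithelial tissue in that library is a candidate explanation. Akr1b7, an aldo-keto reductase abundant in the mouse vas deferens and named after its value was seen, had 4171 CPM in PBS replicate 1 and 0.845 in PBS replicate 2. The design names no biological difference between the PBS libraries, so none was tested.

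Leptin transcripts were lower in both MHE libraries, and by more than the median of the other adipocyte markers. Lep stood 2.10 below the median of the 15 other markers on the log2 scale (a difference of -2.10, against an SD of 0.69). It was the lowest of the 16 markers, at -2.72, and was singled out after its value was seen. Its distance from the others therefore cannot decide whether a lower share of adipocyte RNA was the cause. Across 4 scalings the log2 fold change of Lep was at most -2.54. Those scalings moved the median of all genes only between -0.06 and 0.14, so they could not have undone the fall. They show only that the fall does not depend on which of the 4 was used. An effect of the treatment stays open and untested, since animals, fat mass and feeding are not given in the labels.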
